A study of Mus musculus with 24 samples.

How the data were processed

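The series comprised 24 libraries from 1 pool of hashtagged mammary T cells of wild-type C57BL/6 mice: 8 gene expression, 8 hashtag and 8 T cell receptor libraries, 1 of each kind per lane of a Chromium controller run with 5′ chemistry, per the labels' protocols. The pool held 4 nulliparous, 5 pregnant and 5 lactating mice. Libraries were grouped by kind, as their titles give it, and numbered by lane. Because every lane carried all stages, no library was placed in a stage.

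Cell Ranger 7.1.0, Seurat and the genome build mm10 are named in the submitters' processing notes. The settings for cell calling, for the aggregation of the lanes and for any equalisation of depth are not given in the sources used here. The deposited barcode list holds 1 line per called cell, a 16-base barcode followed by a lane number. The list carries the name of a filtered matrix, and the filter that made it is not described further. The deposited feature list gives an Ensembl gene ID, a symbol and a feature type per line. The deposited hashtag key gives a name and a 15-base sequence per hashtag. The deposited lane list names the 8 lanes in the order of aggregation, with the lane number in each name, and barcodes were assigned to lanes by that number. The values used here are names and barcodes, with no expression value per gene. How cells were called decides how many barcodes a lane shows, so a lane with more free RNA or more debris can differ in called cells for that reason alone. The number of columns belonging to samples outside the label list was 0.

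Called cells were counted per lane and set against the 42000 cells loaded per lane, with Wilson 95% binomial intervals and, as an alternative, exact Clopper-Pearson intervals. Equality of lanes was tested with the variance over the mean, which orders draws as the chi-square does, against 100000 multinomial draws. The number of barcodes the lanes drew from was estimated as the sum over lane pairs of the product of their cell numbers, divided by the sum of the shared barcodes. Overlaps of the 28 pairs were compared with 1000 simulated sets of independent uniform draws of the same sizes. Barcodes that differ at 1 base, or as an alternative at 2 bases, were searched within and between lanes, and the same-lane number was compared with 100000 permutations of the lane labels (both tails). Lanes are technical divisions of 1 pool, so p-values bear only on how cells and barcodes fell among lanes. None of them measures variation between mice. On simulated data of 4 lanes drawing from 60000 barcodes, the mean estimate over 50 data sets was 59765 by pairs and 59740 by maximum likelihood.

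Genes are named from 22 lists of T cell classes, T cell states and other mammary cell types, fixed before the data were examined. The tests of lane counts, of pair overlaps and of neighbouring barcodes, and the alternatives named below, were fixed then too. The count of coincidences among 3 lanes, the comparison of barcode GC content and the arithmetic of doublets were added afterwards. Each list was matched to the feature list by exact symbol, and symbols that RefSeq gives as synonyms of 1 gene were then counted as 1 gene. The results of 2 of the lists are not reported here. Of the 32285 gene IDs, 32158 (99.6%) were found in a table of mouse gene names. A symbol stood on more than 1 row for 38 symbols, none of them in the lists. Coordinates were taken by symbol from the RefSeq annotation of GRCm38.p6, the assembly that mm10 represents, and each of the 133 genes behind the 136 listed symbols had 1 position there.

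The tests between stages (summed counts per mouse, shares of cell classes per mouse) were planned for the case that counts per cell and per hashtag were at hand, and were not run. Alternatives were leaving out barcodes called in several lanes, leaving out each lane in turn, another estimator of the number of barcodes, a distance of 2 bases, matching without regard to letter case, and comparison of hashtags with reverse complements. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.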

Results

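T cells were sorted from the mammary glands of C57BL/6 mice at 3 reproductive stages: nulliparous females that had never carried a litter, pregnant females late in gestation (G18.5), and lactating females at day 5 of lactation. The series title names mammary intraepithelial lymphocytes, T cells that sit within an epithelium, and their part in the onset of milk production, so the comparison the design implies is between T cells of the 3 stages. Each mouse was marked with its own hashtag, a DNA-barcoded antibody, and the marked cells were pooled and divided over 8 lanes of a droplet instrument. Every lane gave 3 libraries (gene expression, hashtags and T cell receptor sequences), 24 libraries in all. All lanes carried the whole pool, so no library belongs to one stage, and the mice, not the lanes, are the biological replicates. The material analysed here was the list of called cells, the list of counted features, the hashtag key and the lane list. Counts per cell, hashtag counts and receptor sequences were not analysed here, so no difference in expression, cell type share or clonality between stages is reported, and the depth of sequencing per cell is unknown.

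The gene list against which the cells were counted covered nearly all genes listed for conventional and unconventional T cells, for tissue residency and for other mammary cell types. It had 32285 genes and 14 hashtags. Of 136 gene symbols in 22 lists fixed before the data were examined, 132 were found exactly, and 20 lists were found with every symbol. The 136 symbols stand for 133 genes, since 3 genes were listed under 2 symbols each, and 132 of the 133 genes were present. Presence in this list shows only that reads of the gene could be counted, not that any cell expressed it. Nor does a place in any of the 22 lists make a gene specific to the cells that the list is named for.

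Among the markers of T cell lineage, all 9 of the alpha beta T cell list were present, including Trac, the constant region of the alpha chain, Trbc1 and Trbc2, the constant regions of the beta chain, and Cd3d, Cd3e and Cd3g, the signalling chains of the receptor complex. All 5 genes of the CD8 list were present, with separate entries for the co-receptor chains Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379171) and Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337492). Some intraepithelial T cells carry the product of Cd8a as a homodimer, without that of Cd8b1. The CD4 list (3 of 3, with Cd4, Cd40lg and the lineage factor Zbtb7b) and the regulatory T cell list (6 of 6, with Foxp3, Il2ra and Ctla4) were also complete.

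All 12 genes of the intraepithelial lymphocyte list were present, among them Itgae (ENSMUSG00000005947, chromosome 11, 73090505 to 73147449), which encodes the CD103 integrin chain that binds E-cadherin on epithelial cells, Cd160, Cd244a, Fcer1g, Tyrobp and the granzyme genes Gzma and Gzmb. The tissue residency list was complete at 8 of 8, including Cd69, Cxcr6, Itga1 and Zfp683, the gene of the transcription factor Hobit. The cytotoxicity list was complete at 8 of 8, with Prf1, Ifng and Ccl5 among its members. Complete lists were also found for genes related to innate-like T cells (4 of 4, namely Zbtb16, Klrb1c, Cd1d1 and Mr1). The lists for cell cycle (8 of 8) and for exhaustion and regulation (6 of 6) were complete too.

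All 7 genes of the gamma delta T cell list, which gives them as 10 symbols, were present. Trdc, the constant region of the delta chain (ENSMUSG00000104876, chromosome 14, 54142851 to 54146108), and Trdv4 were present. The listed constant regions of the gamma chain were present as Tcrg-C1, Tcrg-C2 and Tcrg-C4. The symbols Trgc1, Trgc2 and Trgc4, for which the RefSeq annotation gives these names as synonyms, found no match of their own. A further constant region, Tcrg-C3, was not listed but was present. The interferon response list was found at 7 of 8. Its unmatched member, the only gene of all lists without an entry, was Mx1, an interferon-induced antiviral gene, which RefSeq places on chromosome 16 from 97447035 to 97462906 and classes as a transcribed pseudogene in the C57BL/6J genome.

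The gene list held 268 gene segments of the T cell receptor loci. The alpha chain had 128 variable and 60 joining segments and 1 constant region. The beta chain had 35 variable, 2 diversity and 14 joining segments and 2 constant regions. The delta chain had 6 variable, 2 diversity and 2 joining segments and 1 constant region, and the gamma chain 7 variable and 4 joining segments and 4 constant regions. In the RefSeq annotation of GRCm38, the 166 alpha genes that could be placed spanned 52427967 to 54224198 on chromosome 14. The 10 delta genes that could be placed spanned 53881612 to 54149201, inside the alpha span. Of the 128 alpha variable segments, 10, such as Trav21-dv12 and Trav15-1-dv6-1, carried a delta name as well. A count on one of these 10 segments cannot by itself be assigned to an alpha or a delta chain.

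Genes of the lists for other cells that a mammary sort could carry, and of the hormone receptor list, were also countable. A place in these lists does not make a gene specific to such cells. Klrb1c, for example, stood both in the natural killer and innate lymphoid list and in the innate-like T cell list. All 6 milk protein genes were present, namely Csn1s1, Csn1s2a, Csn2, Csn3, Wap and Lalba. The 4 caseins among them lie together on chromosome 5 between 87666208 and 87932550. The epithelial list (Epcam, Krt8, Krt18, Krt5, Krt14 and the alveolar factor Elf5) was complete at 6 of 6, as were the hormone receptors, including Prlr, the prolactin receptor, and Esr1 and Pgr, the estrogen and progesterone receptors. The lists for B cells (5 of 5), myeloid cells (6 of 6), natural killer and innate lymphoid cells (6 of 6), stroma and endothelium (5 of 5) and red cells and platelets (4 of 4) were complete.

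The hashtag key held 14 hashtags, each named for 1 mouse: 4 nulliparous, 5 pregnant and 5 lactating. The counts match the 14 mice that the sample descriptions list by stage, while the same descriptions give a total of 15 samples. The nulliparous mice were numbered 2 to 5 and the hashtags 2 to 15, whereas the pregnant and the lactating mice were each numbered 1 to 5. All 14 hashtags also appeared among the counted features under the same names. Over the 91 pairs of hashtags, the 15-base sequences differed at a median of 11 positions and at no fewer than 7. A comparison of expression between stages would thus rest on 4 against 5 mice for nulliparous against either other stage, and on 5 against 5 for pregnant against lactating.

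Across the 8 lanes 114629 barcodes of the sorted mammary pool were called as cells, and whether each was a T cell was not examined here. Lane 7 gave the most at 18250 and lane 8 the fewest at 11326, a ratio of 1.61. The other lanes gave 15634 cells in lane 1, 13249 in lane 2, 14259 in lane 3, 12271 in lane 4, 14033 in lane 5 and 15607 in lane 6. The mean was 14329 ± 2179 cells per lane (SD, n = 8 lanes), a coefficient of variation of 15.2%. Counting error alone would give an SD of about 119.7 cells. The variance was 331 times the mean, and 189 times the mean without lane 7. The central 95% of multinomial draws with equal lanes ended at 2.29. A Monte Carlo form of the exact multinomial test gave p = 1e-05, the smallest value that 100000 draws can give. Lanes are divisions of 1 pool, so this test measures technical spread between lanes.

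**Figure D1:**
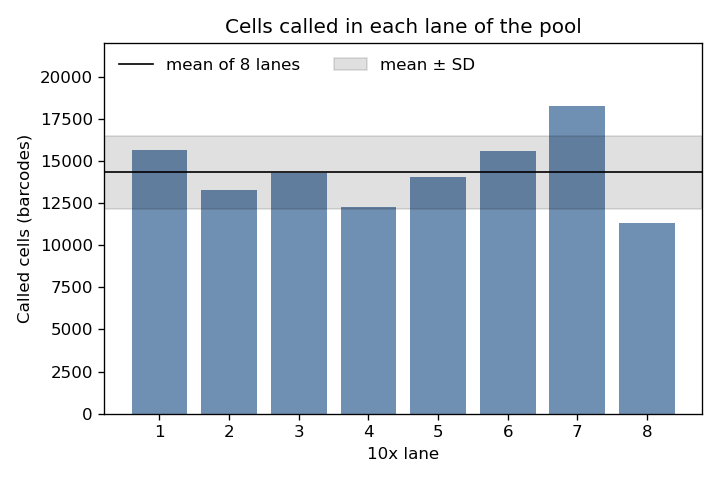
Called cells (vertical axis, number of barcodes) in each of the 8 lanes (horizontal axis), with the mean of the lanes as a line and the mean ± SD as a grey band. Lane 7 at 18250 lies above the band and lane 8 at 11326 below it.

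The labels give 42000 sorted cells loaded per lane, 336000 in all. Called cells made up 34.1% of these (Wilson 95% confidence interval 34.0 to 34.3%). Per lane the share was 34.1% ± 5.19 (SD, n = 8), from 27.0% in lane 8 (Wilson interval 26.5 to 27.4%) to 43.5% in lane 7 (43.0 to 43.9%). The intervals cover counting error only, take the stated load as exact and count a droplet that held several cells as 1 cell.

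Barcode sharing between the cells of different lanes did not depart detectably from independent draws on 1 common set of 16-base barcodes. The 114629 cells carried 107087 distinct barcodes, of which 99843 were called in 1 lane, 6954 in 2 lanes, 282 in 3 lanes and 8 in 4 lanes. The 28 pairs of lanes shared 7848 barcodes in total, from which the lanes were estimated to have drawn on 730384 barcodes, with 95% of 1000 simulated estimates between 714720 and 745878. Overlaps ran from 189 for lanes 4 and 8 (190.3 expected) to 422 for lanes 1 and 7 (390.6 expected), and 14 pairs lay above and 14 below expectation. Observed over expected ranged from 0.901 to 1.09. The chi-square over the 28 pairs was 18.2, within the range of 14.9 to 41.7 that held 95% of simulated values (simulation p = 0.90). Since the number of barcodes was estimated from the same overlaps, the test bears on differences between lane pairs and not on the total. No barcode differed from another at a single base, within a lane or between lanes, so the permutation test planned for such pairs could not be run. At 2 bases there were 124048 pairs in all. Since pairs at 1 base were missing between lanes too, their absence is no evidence that misreads were few.

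**Figure D2:**
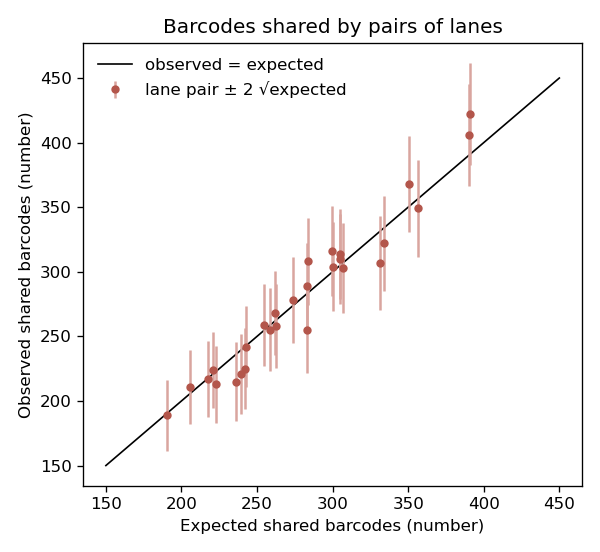
Observed (vertical axis) against expected (horizontal axis) number of barcodes shared by each of the 28 pairs of lanes, with bars of ± 2 times the square root of the expected number and a line where both are equal. The points follow the line from 189 shared barcodes for lanes 4 and 8 to 422 for lanes 1 and 7.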

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

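The mean of 14329 called cells per lane became 12480 when barcodes called in more than 1 lane were left out. Every lane lost a similar share of its cells, from 12.6% in lane 7 to 13.4% in lane 8. The mean ranged from 13768 to 14758 when each lane was left out in turn. The variance over the mean stayed far above equal draws in each of these settings, at 296 without recurring barcodes and from 189 to 386 over the lanes left out. It was 189 without lane 7, so that lane alone accounts for a fall of over 1.5 times, and 259 without lane 8. Lane 7 was not an outlier by Dixon's test. Its gap to the next lane was 0.378 of the range of called cells, below the critical value of 0.526. The estimated number of barcodes drawn from was 731107 by maximum likelihood and ranged from 724158 to 736425 over the lanes left out. Counting 1 member of each pair of one-base neighbours, or leaving such barcodes out, could not change any value because there were 0 such pairs. Widening the distance to 2 bases gave 15779 same-lane pairs. Exact intervals, matching without regard to letter case (132 symbols) and reverse complements of the hashtags (smallest distance 7) left the values as reported. The tests between stages and the alternatives set for them (DESeq2, no filter on low counts, leaving out each mouse, lane as a block, keeping cells with 2 hashtags) were not run. No paired analysis was possible because the hashtag and receptor libraries that share lane numbers with the expression libraries have no values analysed here. Depth per cell is unknown.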

Other observations

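The tests of coincidences among 3 lanes, of barcode GC content and of doublet shares were chosen only after the data had been seen, and the tests of lane counts and pair overlaps, fixed earlier, were set against explanations only after those counts had been seen.

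Zfp683, the gene of the residency factor Hobit, is classed as a pseudogene in the RefSeq annotation of GRCm38 (chromosome 4, 134051195 to 134058941) and yet was among the counted genes as ENSMUSG00000049410. Mx1, classed as a transcribed pseudogene in the same annotation, was not matched by any symbol of the gene list. An interferon score built on Mx1 would lose that member here, whereas a residency score built on Zfp683 would keep it. A search for the gamma chain by the symbols Trgc1, Trgc2 or Trgc4 would find nothing in this gene list. Those genes stand there as Tcrg-C1, Tcrg-C2 and Tcrg-C4, beside the unlisted Tcrg-C3.

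If each of the 14 mice gave equally many cells, 92.9% of droplets that captured 2 random cells would hold cells of 2 different mice and could be recognised by their hashtags. By the same arithmetic 66.3% would mix 2 stages, and 66.7% if the 3 stages rather than the mice were equal. If all 114629 called cells could be assigned, equal mice would have 8188 cells each. These are properties of the design, not measured shares.

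The 8 lanes carried the same pool but differed in called cells with a variance 331 times the mean, against 2.29 at the upper end of the central 95% of equal draws, which argues against counting error alone. Differences in the volume loaded, in droplet capture or in the cell calling threshold stay open, since no value analysed here separates them. No biological explanation was tested, because the lanes hold the same mice.

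Recurring barcodes concern 12.9% of all called cells, so a table of cells joined across lanes by the 16-base barcode without the lane number would merge unrelated cells. The chi-square of 18.2 over the lane pairs is consistent with chance draws from one common barcode set. Transfer of molecules between particular lanes could raise the overlap of those pairs, but only where a barcode was called as a cell in both lanes. The highest ratio was 1.09, for lanes 1 and 2. The overlaps thus cannot decide whether molecules were transferred. Uneven use of the barcode set could raise the coincidences among 3 lanes, which numbered 314 against 306.2 expected. Their ratio of 1.03 lay within the 0.891 to 1.11 of simulated uniform draws. The expected number rested on the number of barcodes estimated from the pair overlaps, which uneven use would raise too. The ratio therefore cannot tell how uneven the use was.

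Misread barcodes called as cells were looked for among pairs that differ at 2 bases. There were 15779 such pairs within lanes against a median of 15819 under permuted lane labels (95% of permutations between 15589 and 16050, permutation p = 0.73), which leaves a small excess possible. Permuted labels alone gave about as many pairs, so the test could show only an excess beyond that range. It covers misreads at 2 bases only and cannot decide whether misread barcodes were called as cells. The mean GC content of called barcodes ran from 50.6% to 50.8% over the lanes, and a permutation of the lane labels gave p = 0.34 for the variance of these means. No difference in GC content was detectable, which leaves open whether lanes differed in which barcodes became cells.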
